A study of Mus musculus with 5 samples.

How the data were processed

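The series holds RNA sequencing of bone marrow-derived macrophages (BMDM) from wild-type C57BL/6 mice. Per the labels, marrow cells were differentiated for 6 days, after which 96% were positive for the macrophage surface proteins F4/80 and CD11b. The cells were then pre-treated with 30 µM CBR-5884, an inhibitor of the enzyme PHGDH, or with solvent, and 10 ng/ml interleukin 4 (IL-4) was added for 24 h. The 5 libraries fall into 2 groups by the treatment label: IL-4 with CBR-5884 (3 libraries, replicates 3, 4 and 5) and IL-4 with solvent (2 libraries, replicates 3 and 5). The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may in part be technical. Cells without IL-4 were not analysed here.

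Total RNA was made into libraries with a directional kit and sequenced as single reads of 75 bp, per the labels' protocols. Bowtie2, TopHat2 and Cufflinks were used with genome build mm10 (GRCm38), per the submitters' processing notes. Their versions, the annotation release and the strand setting are not given in the sources used here. Each deposited file lists transcripts with their exons and, per transcript, an FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library), a 95% interval and a coverage. The deposited FPKM values were estimated by Cufflinks in each library on its own, per the file contents. They cover Ensembl reference transcripts and transcripts that Cufflinks assembled from the reads. No normalization between libraries is recorded.

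Gene identifiers for assembled loci were numbered separately in each library, so the planned sum over a gene identifier of the file could not be compared between libraries. Transcripts were regrouped instead, a choice made after the files were seen. Reference transcripts were assigned to genes through GENCODE mouse release M21 (GRCm38), which matched 70923 of the 71311 reference transcripts (99.5%). An assembled transcript of at least 200 nt was assigned to the gene on its strand that covered at least 50% of its exonic bases. Short assembled transcripts and those without a gene were left out. They held 64.0% to 70.3% of the summed FPKM per library, but 8.5% to 10.1% of the covered bases, since very short transcripts receive very high FPKM. Short reference transcripts were kept. Gene FPKM was the sum over the assigned transcripts. Of 49479 genes, 105 lacked a transcript in some library and were not tested. Mitochondrial transcripts were listed in 1 library alone (37 transcripts in solvent replicate 5, among them those of 13 protein-coding genes), so the mitochondrially encoded list was not tested. Gene coordinates are those of M21, 1-based.

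Coverage divided by FPKM was constant within a library. For reads of 75 bp it implies 30390000, 30230000 and 30700000 fragments in CBR-5884 replicates 3, 4 and 5, and 28850000 and 28310000 in solvent replicates 3 and 5; the fragments themselves were not counted here. Pearson's r between libraries, across the genes above 0 in every library, was 0.984 to 0.985 within groups and 0.978 to 0.981 between groups; genes are not independent replicates. Of reference transcripts above 10 FPKM in both libraries of a pair, 30.6% to 33.5% had 95% intervals that did not meet within groups, so no library was a copy of another. These intervals cover estimation error within a library only.

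The 10773 genes with a mean FPKM of at least 1 were tested. The difference between CBR-5884 and solvent was fitted with limma (lmFit and eBayes with a variance trend, two-sided) on log2(FPKM + 1), with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Standard errors are those of limma. An FPKM of exactly 0 can be a failed estimate. Polr2i, a subunit of RNA polymerase II that all cells use, was at 0 in a whole group, so such genes are described as listed at 0, with each library's value and no fold.

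Gene lists for pathways, cell types and signs of culture or RNA quality (48 lists) were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes, except where a choice is said to have been made later. The 44 lists with at least 3 tested genes were tested with limma's camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation camera also uses the 3 residual degrees of freedom of the fit, which by itself raises p. The iron and heme list had an estimated correlation of -0.047, below the preset, yet its unadjusted camera p rose from 0.00127 to 0.0412. A call lost in that setting can therefore not be put down to correlation between genes alone. Fry tests whether the genes of a list move on balance one way and does not compare the list with other genes. In 9 lists, none of them called, the median, the mean and camera's direction differed in sign.

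Named genes were chosen by rule. The rule takes Phgdh, Psat1, Psph, Shmt1, Shmt2, Arg1, Retnla, Chil3, Mrc1 and Ccl22 in any case. It adds up to 12 called genes per direction with the largest fold change, with groups that do not overlap and a mean FPKM of at least 5 in the higher group. Predicted genes without a proper symbol, ribosomal protein, histone and antigen receptor segment genes are left out. Where fewer than 5 genes pass in a direction, the 8 genes with the smallest unadjusted p are named as well. Up to 4 genes with the smallest p are taken for a called list, and at most 2 for another list. Mgl2, Ccl17, Flt1 and Clec10a were added after their values were seen.

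Alternatives were pseudocounts of 0.1 and 5, no filter on low values or a mean FPKM of at least 5, scaling to TPM, by median ratios or by quantiles, the most abundant reference transcript alone, transcripts of at least 300 nt rescaled, a robust or untrended variance prior, array weights, the replicate number as a block, and each library left out in turn. After the data were seen, 4 more were added: genes above 0 in every library, with and without a robust prior, reference transcripts only, and protein-coding genes only.

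The scripts were tested on simulated data with the real means and spread of 10773 genes, 200 of which were changed in each of 5 draws. Of the changed genes, 32.1% were recovered at 1.5-fold, 62.5% at 2-fold and 85.7% at 4-fold, and 5.5% of the calls were false. All 5 lists shifted by 0.3 on the log2 scale were found. The simulated spread was drawn for each gene on its own, so genes of a list did not vary together. The simulation therefore could not test how list calls behave when genes are correlated. It also set no gene to 0 throughout 1 group, as most genes called in the real data were. The share of false calls therefore does not cover such genes. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.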

Results

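RNA abundance was measured in 5 libraries of mouse bone marrow-derived macrophages that had all received IL-4, the cytokine that drives the alternative (M2) macrophage state. CBR-5884, an inhibitor of the serine synthesis enzyme PHGDH, had been given before IL-4 in 3 of them and solvent in 2. The depth implied by the ratio of coverage to FPKM was 30230000 to 30700000 fragments per library with CBR-5884 and 28310000 to 28850000 with solvent. The design holds 1 comparison, CBR-5884 against solvent under IL-4, which asks how the inhibitor changes the transcriptome of macrophages responding to IL-4. Values below are gene FPKM as mean ± SD over the 3 CBR-5884 and the 2 solvent libraries, and fold changes are on the log2(FPKM + 1) scale with limma's standard error (SE).

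None of the 3 tested genes of serine and glycine synthesis passed the test. Phgdh, which encodes the enzyme of the committed step (chromosome 3, 98313170 to 98339990, GRCm38), was at 1.08 ± 0.20 FPKM with CBR-5884 and 1.28 ± 0.18 with solvent. Its log2 fold change was -0.13 (SE 0.15, limma adjusted p = 0.665). Psat1, the transaminase that follows it, was at 9.73 ± 2.15 and 13.1 ± 1.57 FPKM (log2 fold change -0.41, SE 0.20, limma adjusted p = 0.338). Shmt2, which turns serine into glycine in mitochondria, was at 8.02 ± 1.25 and 10.1 ± 0.25 FPKM (log2 fold change -0.31, SE 0.13, limma adjusted p = 0.285). Its exons overlap those of Ndufa4l2 by 32 nt on the opposite strand, and an effect of this on the value was not tested. Psph and Shmt1 were listed at 0 in all 5 libraries and were not tested. The 3 tested genes of the list had a median log2 fold change of -0.31, and the list was not called (camera adjusted p = 0.278). None of the 3 passed when adjusted over the list alone.

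Genes that IL-4 induces in macrophages were lower with CBR-5884 as a list, with single genes moving both ways. The median log2 fold change of the 32 tested genes was -0.34, with 23 negative and 9 positive (camera adjusted p = 0.00437). The call was lost with an estimated correlation (adjusted p = 0.572). Lists of monocyte and dendritic cell markers, with 5 and 4 tested genes, had medians of -0.31 and -0.36 and were not called (camera adjusted p = 0.209 and 0.133). Over all genes tested 1 gene fell, 0 rose and 31 did not pass; adjusted over the list alone, 11 fell and 4 rose. The gene that fell was Tgm2, the transglutaminase used as an M2 marker in mouse and human (chromosome 2, 158116402 to 158146436), from 62.6 ± 3.87 to 37.0 ± 0.75 FPKM. Its log2 fold change was -0.74 (SE 0.06, limma adjusted p = 0.0467), and the call was lost when any 1 library was left out (adjusted p up to 0.194). Its value is uncertain in part, since 370 nt of its exons overlap Rprd1b on the opposite strand and the strand setting of the estimates is not known.

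The other genes of this list did not pass the threshold, among them those with the largest fold changes of the list in size. Retnla, which encodes the secreted M2 marker RELMα (chromosome 16, 48842551 to 48844461), was at 1259, 1539 and 1619 FPKM with CBR-5884 and at 5300 and 7587 with solvent. Its log2 fold change was -2.11 (SE 0.20, limma adjusted p = 0.0645). Arg1, the arginase that competes with nitric oxide synthase for arginine (chromosome 10, 24915221 to 24927484), was at 92.1 ± 11.1 and 265.1 ± 56.6 FPKM (log2 fold change -1.51, SE 0.18, limma adjusted p = 0.0847). Rnase2a was at 78.9 ± 4.36 and 185.3 ± 34.7 FPKM (limma adjusted p = 0.0833), and Ptgs1, a cyclooxygenase, at 55.1 ± 3.35 and 83.1 ± 0.76 (limma adjusted p = 0.0844). Mgl2, Ccl17, Flt1 and Clec10a, chosen after their values were seen, had log2 fold changes of -1.84, -1.11, -1.10 and -1.09 (limma adjusted p = 0.11, 0.333, 0.132 and 0.132). Chil3, a chitinase-like protein, was at 1232 ± 135 FPKM with CBR-5884 and 919 ± 28.6 with solvent (limma adjusted p = 0.168). Mrc1, the mannose receptor, was at 183 ± 19.9 and 209 ± 8.71 FPKM (limma adjusted p = 0.381). The chemokine gene Ccl22 was at 6.69, 22.4 and 25.1 FPKM with CBR-5884 and at 21.2 and 31.6 with solvent (limma adjusted p = 0.583).

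**Figure D1:**
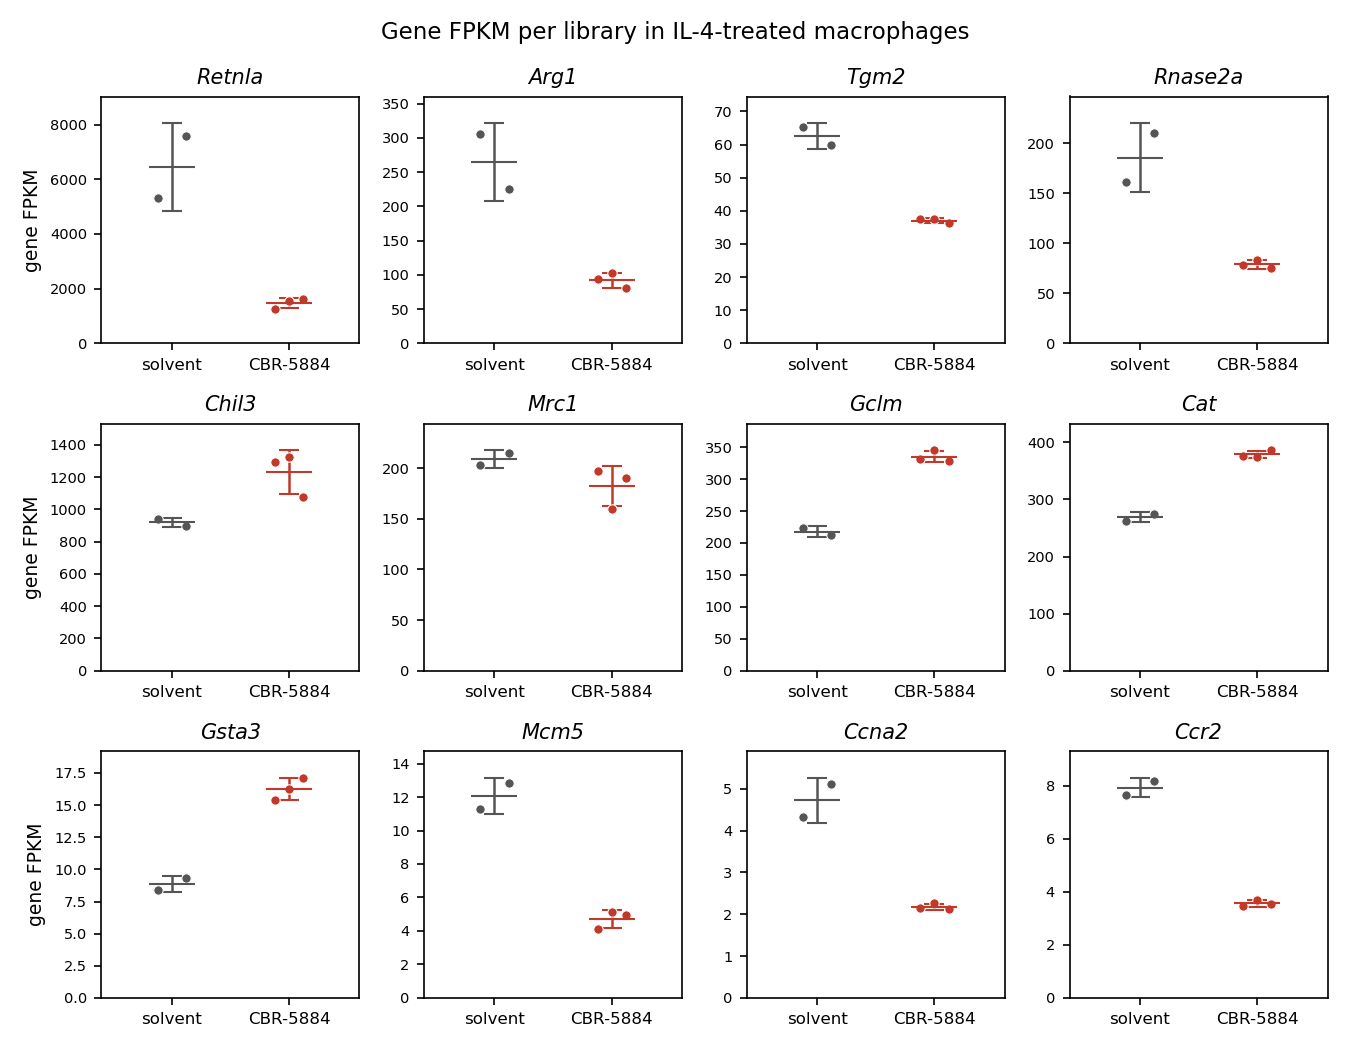
Gene FPKM (linear axes from 0) of 12 genes in the 2 solvent and 3 CBR-5884 libraries; dots are libraries, horizontal lines are means and bars are SD. Retnla lies between 1259 and 1619 FPKM with CBR-5884 and at 5300 and 7587 with solvent; of the 12 genes, Tgm2, Gclm and Ccr2 passed the limma test.

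Targets of NRF2, the transcription factor of the antioxidant response, were higher with CBR-5884. Of 38 tested genes 35 had a positive log2 fold change, with a median of 0.29 (camera adjusted p = 7.7e-17; adjusted p = 0.4 with an estimated correlation). Over all genes tested 1 rose, 0 fell and 37 did not pass; adjusted over the list alone, 23 rose and 0 fell. Gclm, the modifier subunit of the enzyme that limits glutathione synthesis (chromosome 3, 122245557 to 122270732), rose from 218 ± 8.35 to 335 ± 8.87 FPKM (log2 fold change 0.62, SE 0.05, limma adjusted p = 0.0479). That call was lost when any 1 library was left out (adjusted p up to 0.19). Cat, which encodes catalase, was at 379 ± 6.50 FPKM with CBR-5884 and 269 ± 9.21 with solvent (limma adjusted p = 0.0596). The glutathione transferase Gsta3 was at 16.3 ± 0.87 and 8.86 ± 0.63 FPKM (limma adjusted p = 0.0615), and the microsomal one, Mgst1, at 705 ± 20.4 and 532 ± 9.87 (limma adjusted p = 0.0833). With reference transcripts only, an alternative chosen after the data were seen, the log2 fold change of Mgst1 turned from 0.41 to -0.29.

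Cell cycle genes were lower with CBR-5884. All 21 tested genes of the G2/M list had a negative log2 fold change (median -0.76, camera adjusted p = 5.2e-11; adjusted p = 0.4 with an estimated correlation). So did all 20 of the S phase list (median -0.48, camera adjusted p = 2.1e-10; adjusted p = 0.4 with an estimated correlation). Over all genes tested 1 gene of each list fell, and 20 and 19 did not pass; adjusted over the list alone, 17 and 13 fell and 0 rose. In the G2/M list Ube2c, which encodes a ubiquitin-conjugating enzyme of mitotic exit, fell from 4.20 ± 0.10 to 0.58 ± 0.12 FPKM (log2 fold change -1.72, SE 0.12, limma adjusted p = 0.0407). The call was lost when any 1 library was left out (adjusted p up to 0.162), and the value is uncertain because 592 nt overlap Tnnc2 on the opposite strand. The cyclin gene Ccna2, which overlaps Exosc9 on the opposite strand, was at 2.18 ± 0.07 FPKM with CBR-5884 and 4.72 ± 0.55 with solvent (limma adjusted p = 0.0844). Mki67, a proliferation marker, was at 1.24 ± 0.24 and 3.42 ± 0.28 FPKM (limma adjusted p = 0.1). Mcm2 and Mcm5, helicase subunit genes of the S phase list, were at 3.42 ± 0.14 and 4.73 ± 0.54 FPKM with CBR-5884 and at 7.19 ± 0.52 and 12.1 ± 1.10 with solvent (limma adjusted p = 0.0508 and 0.0645). Among genes with a mean FPKM of at least 5 the G2/M median was -0.66 and the list was not called (camera adjusted p = 0.0976). The S phase gene that was called, Mcm7, was listed at 0 in the 3 CBR-5884 libraries and at 7.34 and 8.15 FPKM in the solvent libraries; without genes listed at 0 the S phase median was -0.43.

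Genes of protein synthesis and respiration shifted by smaller amounts. Of 52 tested ribosomal protein genes 51 had a negative log2 fold change, with a median of -0.19 (camera adjusted p = 8.5e-14; adjusted p = 0.4 with an estimated correlation). Rpl19 was at 346, 354 and 362 FPKM with CBR-5884 and at 459 and 447 with solvent (limma adjusted p = 0.0847). Rps14 was at 566 ± 26.4 and 848 ± 60.0 FPKM (limma adjusted p = 0.0847), but its log2 fold change was positive when assembled transcripts were left out. Nuclear genes of oxidative phosphorylation had a median of -0.14 over 75 genes, 64 of them negative (camera adjusted p = 6.5e-07; adjusted p = 0.572 with an estimated correlation). Cox8a, a subunit of cytochrome oxidase, was at 395.5 ± 3.74 FPKM with CBR-5884 and 523 ± 21.4 with solvent (limma adjusted p = 0.0833). Neither list had a gene that passed over all genes tested; adjusted over the list alone, 30 ribosomal protein genes and 17 respiration genes fell and 0 rose. Ribosome biogenesis genes had a median of -0.15 over 25 genes (camera adjusted p = 0.00437; adjusted p = 0.728 with an estimated correlation), and 1 fell by either adjustment and 0 rose. That gene, Dkc1, was listed at 0 in the 3 CBR-5884 libraries and at 6.74 and 6.96 FPKM with solvent. The call of this list was lost without solvent replicate 5 (camera adjusted p = 0.0577).

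Cholesterol synthesis and iron handling genes were higher as lists. The 21 tested cholesterol synthesis genes had a median log2 fold change of 0.18, with 18 positive (camera adjusted p = 0.00123; adjusted p = 0.728 with an estimated correlation). It was the 1 called list that did not pass limma's fry (adjusted p = 0.433). None passed over all genes tested or adjusted over the list alone, and Hmgcs1, an early enzyme of the pathway, was at 59.1, 63.2 and 52.3 FPKM with CBR-5884 and at 49.5 and 43.0 with solvent (limma adjusted p = 0.226). The 15 tested iron and heme genes had a median of 0.135, with 13 positive (camera adjusted p = 0.00623; adjusted p = 0.4 with an estimated correlation). Over all genes tested none passed; adjusted over the list alone, 1 rose and 1 fell. The ferritin gene Fth1 was at 15180, 14320 and 14350 FPKM with CBR-5884 and at 11750 and 10720 with solvent (limma adjusted p = 0.117). Hfe, the gene with the smallest p of the list, was lower, at 64.0, 67.9 and 68.5 FPKM with CBR-5884 and at 84.0 and 85.0 with solvent (limma adjusted p = 0.112). Fth1, Hmox1, Ftl1, Blvrb and Slc48a1 are also in the NRF2 list, so the iron and heme result is not independent of that list. Without solvent replicate 5 both calls were lost: the cholesterol synthesis median moved to 0.08 (camera adjusted p = 0.186) and the iron and heme median to 0.16 (camera adjusted p = 0.0577). The iron and heme call was also lost with quantile normalization (camera adjusted p = 0.0821). With the most abundant reference transcript and with reference transcripts only its median was 0.07 (camera adjusted p = 0.201 and 0.0948).

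**Figure D2:**
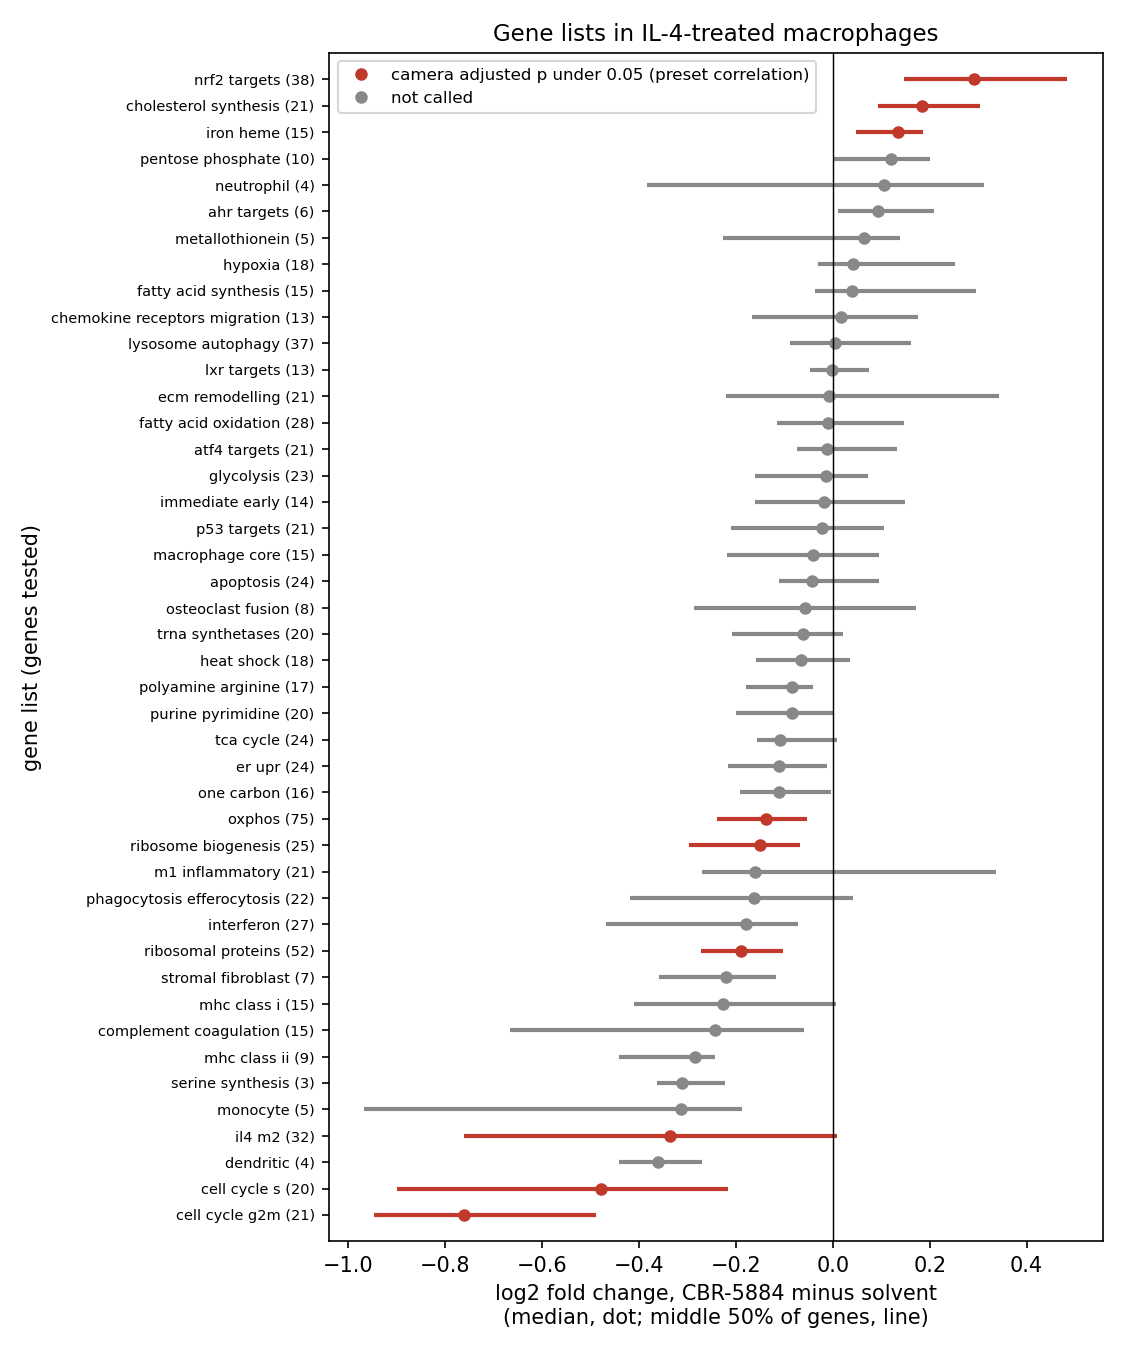
Median log2 fold change (dot) and the middle 50% of genes (line) for each of the 44 tested gene lists, CBR-5884 minus solvent, with the number of genes tested in brackets. The 9 lists called by camera with the preset correlation are in red, 3 above 0 and 6 below; with an estimated correlation camera called 0, and 5 had an unadjusted p below 0.05.

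Lists for the stress responses and for metabolism beyond these were not called, although the hypoxia list was called in 13 of 24 alternatives (adjusted p = 0.0283 to 0.537). Of the other lists in this group, the pentose phosphate list was called in 4 alternatives, the tricarboxylic acid cycle in 3, the unfolded protein response in 2, and nucleotide synthesis and polyamine and arginine genes in 1 each. The targets of ATF4, the transcription factor of the amino acid response, had a median log2 fold change of -0.01 over 21 genes (camera adjusted p = 0.522), with 10 positive and 11 negative. Adjusted over the list alone, 2 of them rose and 3 fell. Slc7a11, the cystine transporter, was at 17.3, 17.5 and 15.3 FPKM with CBR-5884 and at 10.7 and 8.49 with solvent (limma adjusted p = 0.12). It is also in the NRF2 list, as are G6pdx, Pgd, Tkt and Taldo1 of the pentose phosphate list. The tRNA synthetases had a median of -0.06 (camera adjusted p = 0.28; 4 fell adjusted over the list alone), one-carbon genes -0.11 (0.328), the unfolded protein response -0.11 (0.267), heat shock genes -0.07 (0.643), p53 targets -0.02 (0.974) and apoptosis genes -0.04 (0.815). Glycolysis genes had a median of -0.02 (camera adjusted p = 0.824), the pentose phosphate pathway 0.12 (0.0747; 2 rose and 1 fell adjusted over the list alone), the tricarboxylic acid cycle -0.11 (0.0851) and hypoxia genes 0.04 (0.054; 5 rose and 1 fell adjusted over the list alone). Nucleotide synthesis genes had a median of -0.09 (camera adjusted p = 0.206; 3 fell adjusted over the list alone) and polyamine and arginine genes -0.08 (0.325; 1 fell adjusted over the list alone). Limma's fry, which does not compare a list with other genes, passed 13 lists, 8 of them called by camera. The others were the hypoxia, polyamine and arginine, complement and monocyte lists (adjusted p = 0.0283 each) and the pentose phosphate list (adjusted p = 0.0414).

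Over all 10773 genes tested, limma called 5 genes higher and 19 lower with CBR-5884; at an unadjusted p below 0.05 there were 781 and 1335. That balance depended on the scaling, with 1144 higher and 947 lower at an unadjusted limma p below 0.05 on the TPM scale, 1156 and 947 after quantile normalization, 1130 and 1005 with transcripts of at least 300 nt rescaled, and 1015 and 1087 with median ratios. Of the called genes above 0 in every library, Gda, a guanine deaminase gene (chromosome 19, 21391307 to 21473445), fell from 46.3 ± 5.64 to 13.7 ± 1.33 FPKM (log2 fold change -1.69, SE 0.12, limma adjusted p = 0.0404). Ccr2, the receptor that draws monocytes to CCL2 (chromosome 9, 124101950 to 124113557), fell from 7.93 ± 0.37 to 3.57 ± 0.13 FPKM (log2 fold change -0.97, SE 0.07, limma adjusted p = 0.0394). The annexin gene Anxa3 fell from 314 ± 28.6 to 160 ± 6.81 FPKM (log2 fold change -0.97, SE 0.08, limma adjusted p = 0.049). These 3 calls were lost when any 1 library was left out (adjusted p up to 0.148, 0.173 and 0.196). Over 22 alternatives Gda was called in 12, Ccr2 in 10, Gclm in 7, and Anxa3 and Tgm2 in 6 each; Ube2c was called in 8 of 21. The log2 fold change of Anxa3 was -0.52 with the most abundant reference transcript (limma adjusted p = 0.386), and with a pseudocount of 5 those of Ccr2 and Ube2c were -0.59 and -0.72. Anapc10 was at 3.08 ± 0.18 and 14.4 ± 0.62 FPKM (limma adjusted p = 0.00356), but its log2 fold change turned from -1.92 to 0.28 when transcripts assembled by Cufflinks were left out. Among genes not called, those with the smallest unadjusted p and higher values with CBR-5884 were Ywhaq (65.6 ± 0.99 against 41.3 ± 2.49 FPKM, limma adjusted p = 0.0508) and Serpinb9 (8.21 ± 0.47 against 4.75 ± 0.0015 FPKM, limma adjusted p = 0.0704), beside Cat and Gsta3. Snord83b was at 226, 75.5 and 75.3 FPKM with CBR-5884 and listed at 0 in both solvent libraries (limma adjusted p = 0.0508).

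The other 17 of the 24 called genes were listed at 0 in every library of one group, 4 of them in both solvent libraries and 13 in all CBR-5884 libraries. A group at 0 throughout adds no spread, so the p-values of these genes rest on the spread of the other group and on limma's variance prior. They are therefore not comparable with those of other genes. Elob, an elongin subunit gene, was at 213, 194 and 219 FPKM with CBR-5884 and listed at 0 with solvent, and Polr2i was at 20.3, 21.1 and 20.7 FPKM and listed at 0 with solvent (limma adjusted p = 3.3e-05 and 7.8e-05). Il4i1, an IL-4-induced amino acid oxidase gene, was listed at 0 in the 3 CBR-5884 libraries and at 44.3 and 44.0 FPKM with solvent (limma adjusted p = 7.5e-05). Pik3r2 was listed at 0 in the same 3 libraries and at 17.1 and 16.1 FPKM with solvent, and the ribosomal RNA gene n-R5s54 at 32.3 and 34.1 (limma adjusted p = 0.0005 and 1e-04). The values of n-R5s54 (chromosome 13, 52964621 to 52964732) and of Snord83b (chromosome 15, 80078498 to 80078591) are uncertain, since very short transcripts receive very high FPKM. Elob, Polr2i, Il4i1, Mcm7 and Dkc1 each share exonic positions with a neighbouring gene on the opposite strand, and their values are uncertain. The overlap on that strand was 325 nt for Polr2i, 3505 nt for Il4i1 and 385 nt for Mcm7, but 4 nt for Elob and 45 nt for Dkc1. Il4i1 also had 97 nt of exonic overlap on its own strand. Pik3r2 and n-R5s54 had no exonic overlap with another protein-coding gene, so overlap of that kind does not account for every gene listed at 0. Overlap with noncoding genes or assembled transcripts was not counted. Genes listed at 0 in exactly the solvent pair numbered 7, and in exactly the 3 CBR-5884 libraries 11, against 3 to 9 and 2 to 10 for other sets of as many libraries, among genes with a mean of at least 5 FPKM elsewhere. When only genes above 0 in every library were tested, an alternative chosen after the data were seen, limma called 0 genes higher and 1 lower (742 and 1341 at an unadjusted p below 0.05). The 1 gene was Anapc10, and the calls of Gclm, Tgm2, Ube2c, Gda, Ccr2 and Anxa3 were lost (limma adjusted p = 0.071 to 0.0782). Those calls therefore depended in part on the genes listed at 0 being tested with them. The split of 5 higher and 19 lower became 8 and 16 on the TPM scale and 8 and 17 after quantile normalization.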

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

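Tests on genes above 0 in every library, reference transcripts only and protein-coding genes only were chosen after the data were seen; the other alternatives were planned. Against 5 genes higher with CBR-5884, there were 3 with a pseudocount of 5 and 3 at a mean FPKM of at least 5, 8 each with TPM, median-ratio and quantile scaling, 14 with the most abundant reference transcript, 19 with reference transcripts only and 0 among genes above 0 in every library, with or without a robust prior (742 and 738 at an unadjusted limma p below 0.05). Against 19 lower, there were 11 with a pseudocount of 0.1, 33 without a filter, 6 at a mean FPKM of at least 5, 12 among protein-coding genes and 1 among genes above 0 in every library, with or without a robust prior. That setting removes genes listed at 0, but 6 of the 19 were above 0 in every library. Of these, Gda, Ccr2, Anxa3, Tgm2 and Ube2c kept their fold changes there and lost the call (limma adjusted p = 0.071 to 0.0801). Anapc10 was the 1 gene still called. Benjamini-Hochberg adjustment ranks all genes tested together, so genes listed at 0 with small p-values had lowered the adjusted p of these genes. The variance prior changed as well (1.51 to 1.96 degrees of freedom), and these effects were not separated. Leaving out 1 library gave 8 to 11 higher and 11 to 78 lower; the 78 and 57 came without solvent replicates 3 and 5, where the lone solvent library is assumed to vary like the others, and the 11 without CBR-5884 replicate 3. Against 3 lists higher and 6 lower, there were 5 and 12 without a filter, 5 higher at a mean FPKM of at least 5 and 5 with transcripts of at least 300 nt, 10 lower with reference transcripts only, and 0 and 0 with camera's estimated correlation, where 5 of 44 had an unadjusted p below 0.05. Leaving out 1 library gave 1 to 5 lists higher (1 without solvent replicate 5) and 5 to 12 lower (12 without CBR-5884 replicate 4). The IL-4-induced list (median -0.337) was called in 23 of 24 alternatives, with medians of -0.494 to -0.199, and lost its call with the estimated correlation (adjusted p = 0.572). The serine synthesis list was called in none and had too few genes at a mean FPKM of at least 5. Anapc10 turned to 0.366 with the most abundant reference transcript and 0.284 with reference transcripts only, which leave out an assembled transcript. Where not named, the cause was not tested. Of 2681 other values for named genes 2566 kept their side of the threshold, and of 1008 for other lists 928 did. The sign changed in 23 and 42. Most named genes were not called to begin with, so these totals say little about how stable the calls were. Among named genes 92 values were calls lost, 2 were calls reversed and 21 were calls gained. Among other lists 16 were lost and 64 gained. Limits by depth were not compared between expression levels.

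With the replicate number as a replicate block, which leaves 1 residual degree of freedom, 2 genes were higher and 1 lower, and 4 lists were higher and 12 lower. The labels do not say whether replicates 3 and 5 share more than a number. Deviations of same-numbered libraries from the group means correlated at 0.07 and 0.082, and those of other pairs across groups at -0.082 to 0.019. With 2 solvent libraries these values come in pairs of opposite sign, so they cannot decide whether the numbers mark a pairing.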

Other observations

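Of the tests below, those of exonic overlap, of macrophage markers and of the splits of the libraries were chosen after the result was seen; the others were written down before.

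Lists for phagocytosis, lipid handling, lysosomes and matrix were not called, and none of their genes named here passed the test. Cd36, the scavenger receptor for oxidized lipids, was at 1487, 1763 and 1648 FPKM with CBR-5884 and at 987 and 1100 with solvent (limma adjusted p = 0.11), while Cd163, the haptoglobin-hemoglobin receptor, was at 0.35, 0.50 and 0.54 against 3.04 and 1.82 (limma adjusted p = 0.128). The phagocytosis list had a median log2 fold change of -0.16 (camera adjusted p = 0.202; 1 rose and 5 fell adjusted over the list alone). Medians were 0.005 for lysosome and autophagy genes (camera adjusted p = 0.245; 5 rose and 3 fell adjusted over the list alone), -0.01 for fatty acid oxidation (0.535; 1 rose), 0.04 for fatty acid synthesis (0.0605; 2 rose; called in 7 of 24 alternatives), -0.001 for LXR targets (0.53) and -0.06 for osteoclast and fusion genes (0.325). Matrix genes had a median of -0.01 (camera adjusted p = 0.525; 4 rose and 3 fell adjusted over the list alone), and the collagenase genes Mmp8 and Mmp13 were at 92.8, 82.5 and 81.3 and at 23.3, 24.7 and 20.3 FPKM with CBR-5884, against 58.9 and 53.6 and against 14.4 and 14.4 (limma adjusted p = 0.102 and 0.115).

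Immune lists were not called, although MHC class II, complement, interferon and dendritic cell genes were called in 9, 7, 6 and 5 of 24 alternatives. Medians were -0.18 for interferon genes (camera adjusted p = 0.12), -0.16 for M1 inflammatory genes (0.82; 1 fell adjusted over the list alone), -0.28 for MHC class II (0.0747), -0.23 for MHC class I (0.204), -0.24 for complement and coagulation (0.0712; 1 rose and 6 fell) and 0.02 for chemokine receptors (0.808; Ccr2 fell). Fn1, the fibronectin gene, was at 56.5, 76.1 and 46.5 FPKM with CBR-5884 and at 134 and 116 with solvent (limma adjusted p = 0.139). Among markers of other cell types, monocyte genes had a median of -0.31 (camera adjusted p = 0.209; 1 rose and 2 fell adjusted over the list alone, and Ccr2 fell over all genes tested), dendritic cell genes -0.36 (0.133), neutrophil genes 0.11 (0.328; 1 rose) and fibroblast genes -0.22 (0.524). Lists with fewer than 3 tested genes were not tested: in the lymphocyte list Ighm had a log2 fold change of 0.23, in the mast cell list Siglecf 0.12, and in the erythroid and megakaryocyte list Ppbp 0.55 and Pf4 -0.19 (limma adjusted p = 0.78, 0.878, 0.171 and 0.661). The list of mitochondrially encoded genes had 0 tested genes. Immediate early genes had a median of -0.02 (camera adjusted p = 0.824), metallothioneins 0.06 (0.824) and targets of the aryl hydrocarbon receptor 0.09 (0.258; 1 rose adjusted over the list alone). Nqo1, a quinone reductase gene in both that list and the NRF2 list, was at 28.7, 35.4 and 32.7 FPKM with CBR-5884 and at 19.4 and 21.9 with solvent (limma adjusted p = 0.13).

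Genes listed at 0 throughout a group made up most of the called genes. Of 8 such protein-coding genes with a mean of at least 5 FPKM in the other group, 5 overlapped exons of another protein-coding gene (62.5%), against 2049 of 9752 genes never listed at 0 (21%; odds ratio 6.27, Fisher's exact p = 0.013, two-sided). The overlaps of some of these same genes prompted that comparison, so it leaves failed estimates at overlapping loci open without deciding for them. An overlap of any length was counted, such as the 4 nt of Elob and the 45 nt of Dkc1. If the treatment had switched genes on, the solvent pair would stand out. At 0 in exactly that pair were 7 genes, and up to 9 in another of the 10 pairs. That shortfall lies within the margin written down before, so it cannot decide whether genes were switched on. For genes switched off, 11 were at 0 in exactly the CBR-5884 libraries and up to 10 in another set of 3, so a treatment effect on some of them cannot be told apart from zeros that fall by chance on a group.

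The negative list medians of ribosomal protein and respiration genes, of which none passed over all genes tested, could reflect a bias against short, abundant transcripts. In 10000 random lists matched on exonic length and mean FPKM, 0% had a median as low as the -0.19 of ribosomal protein genes (lowest -0.171) and 0.6% as low as the -0.139 of oxidative phosphorylation genes, which argues against that bias as the whole cause. Matched lists ignore the correlation between genes of a list. No biological explanation was tested apart from the treatment itself.

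A lower share of macrophages with CBR-5884 might lower IL-4-induced genes. The 15 macrophage markers had a median log2 fold change of -0.042 (SD of the genes 0.244; camera adjusted p = 0.824; 1 rose and 1 fell adjusted over the list alone), above the -0.337 of the IL-4 list by more than that SD, which argues against it. Monocyte and dendritic cell markers had medians of -0.314 and -0.362, near that of the IL-4 list, so a change in such cells stays open and was not tested. The IL-4 list shares Chil3 with the monocyte list and Batf3 with the dendritic cell list, so these medians are not fully independent of it. An effect of the compound on the IL-4 response, or on another target, stays open and was not tested.

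The 10 splits of the libraries into 3 and 2 are too few for a share below 0.1. The real split called 24 genes and the highest other split 14, so 1 of 10 splits reached the real number. At an unadjusted limma p below 0.05 there were 2116 genes in the real split and 218 to 742 in the others. The real split called 9 lists, and 5 of 10 splits, the real one included, called as many. The highest other split called 17. A split that pairs 2 CBR-5884 libraries sets them against both solvent libraries and the remaining CBR-5884 library, so it keeps part of the treatment difference. Such splits called 8, 17 and 11 lists, so the list counts do not measure chance alone and cannot decide the question.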
